A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

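The 4 genotypes of Schizosaccharomyces pombe were hybridised to 1 Agilent 60-mer tiling array each, per the labels with Cy5 on DNA precipitated with an anti-FLAG gel and Cy3 on whole-cell extract DNA, both amplified by random-primed PCR. The 4 arrays came from 1 slide and 1 scan, per the file headers, so slide and scan do not differ between genotypes. Before hydroxyurea the cells grew in 8% glucose, per the labels' protocols. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 12.0.3.1, per the file headers: raw medians, background-subtracted signals, and processed signals that are also normalised between dyes with 1 linear factor per channel. The deposited series matrix holds a linear Cy5 over Cy3 ratio; in all 43993 probes of each array it equals the ratio of the processed signals to within 1e-06 on the log2 scale, so its scale and direction are known, and it is not centred (column medians 0.985 for WT, 0.971 for clr3D, 1.01 for IRD2 and 1.00 for the double mutant).

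The main value was log2 of processed Cy5 over processed Cy3, minus the median of the array, with no loess or quantile step, as most probes of a histone ChIP carry signal. Control spots (1227 per array) and spots marked as outliers (9 in WT, 21 in clr3D, 20 in IRD2, 11 in the double mutant) were left out; no spot was saturated. Median processed signals were 1114 in Cy3 and 1084 in Cy5 for WT, 1146 and 1093 for clr3D, 1057 and 1062 for IRD2, and 1069 and 1062 for the double mutant. With 1 array per genotype, the number of arrays limits the precision.

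Probe coordinates are those of the files; the headers name no genome build, and the build of the reference annotation was not taken to be the same. The whole-cell extract signal, averaged over the 4 arrays, was instead correlated with the GC content of the reference sequence at shifted positions, in 30 windows of 1500 probes or fewer. All 30 had their best offset within 5 bp of the one obtained if each assembly gap, 100 bp in the reference, were 1000 bp in the array's coordinates (r at the best offset from 0.129 to 0.63, smallest lead over another offset 0.0336). The windows did not cover the short pieces around nmt1 (39 probes) and inv1 (59 probes) on chromosome III or that on chromosome I (99 probes). The placement of these pieces was not checked. Gene names rest on this inferred placement, and only the files' own coordinates are printed. The mating-type contig was matched to chromosome II by its signals in both parts where they share tiles. Its middle has no counterpart in the reference and was analysed by the contig's own coordinates.

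Tiles cover 1000011 to 3049820 of chromosome II with a gap inside the centromere, its right end, the left end of chromosome III, and short pieces around nmt1 and inv1 on chromosome III and on chromosome I. The planned centromeres of chromosomes I and III, the other chromosome ends, mitochondrial DNA and clr3 were not analysed here. Centromere II was taken as the gap between rpb1 and yox1, divided by its tRNA clusters; the mating-type region lay between rpp202 and emc3, and the chromosome end was the outer 50 kb. The segments lost in IRD2 and the 22 probes without extract DNA in any array stay in the medians of the mating-type region. The tRNA clusters, the ribosomal RNA genes of the left end of chromosome III and the DNA beyond them were added as domains after the data were examined. A gene's value was the mean over its probes, with at least 3 probes; for tRNA genes 500 bp on either side were included.

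For each domain the median over probes was set against 10000 random stretches of as many consecutive probes on the arms. For each gene list the median over genes was set against 10000 random lists, for differences drawn among the 50 genes closest in mean ratio to each member. Random lists held protein-coding genes only, also for the tRNA genes. The median ratio of the tRNA genes lay below all random lists in each array, so their percentiles compare unlike genes. Lists with fewer than 3 measured genes have values only. The 11 lists, the 2 gene sets taken from the annotation (ribosomal protein and tRNA genes), the domains planned, the tests and the other settings listed first below were fixed before the data were examined. The genes named for each difference were the 10 with the highest and the 10 with the lowest difference among genes whose probes all differed in the same direction; for the 2 terms of the fit they were the 10 with the largest change in each direction among those past an adjusted p of 0.05, or all where fewer passed. List members may also be named as examples.

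The additive fit of each gene on clr3 and IR state used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment. It was tested on simulated data with 20 runs for the clr3 term over 897 genes: with noise at the spread the fit uses (SD 0.084), 81.0% of genes changed by 0.3 were called, and 1.02% of unchanged genes. Noise at the median gene's residual SD (0.05), which is below that spread, gave 99.9% and 1.09%. Each simulation gave every gene the same noise, as the fit assumes, so it does not test that assumption. The random stretches were tested on simulated data too: of 20 repeats with stretches of 500 probes, 20 with a change of 0.3, 9 with a change of 0.1 and 0 with none lay outside the central range. The unchanged values were drawn from the random stretches themselves. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

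Alternatives were normexp background correction (offset 50), loess within each array, the series matrix, centring on arm probes, scaling to one median absolute deviation, probes well above background only, probes matching 1 place in the reference, domains extended by 5 kb, means over probes, 1 or 5 probes per gene, and 1 factor alone in the fit. The design named mean spot signals for normexp; raw median signals were used in their place. A 100 kb chromosome end was not run, as the tiles used here span 50 kb. Added after the data were seen were Cy5 alone for domains and lists, the mating-type region without probes whose WT extract signal is over 4 times the array median, the gene correlation without heterochromatin genes, robust eBayes, each gene's own spread without moderation, the signs of the domain differences and the contrast of the clr3 difference between backgrounds under other settings, and all alternatives of single named genes.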

Results

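Newly made histone H3 was mapped along part of the genome of the fission yeast Schizosaccharomyces pombe in 4 genotypes: wild type (WT), clr3D, IRD2 and the double mutant IRD2 clr3D. Clr3 is a histone deacetylase that acts in heterochromatin; the labels do not define IRD2. Cells held in S phase by 15 mM hydroxyurea for 4 h were moved to 4% sucrose, still with hydroxyurea, for 2 h, which turns on a plasmid-borne FLAG-tagged H3. FLAG-bound DNA (Cy5) was hybridised against whole-cell extract DNA (Cy3) on a tiling array, so that a high Cy5/Cy3 ratio marks DNA where new H3 had entered chromatin. Each genotype has 1 array. No difference between 2 arrays therefore has a replicate check or a test, and percentiles among random stretches or lists describe these arrays only. In every array at least 43811 of 43993 probes were well above background in both channels, and near-identical tiles at neighbouring positions differed by a log2 ratio SD of 0.07 per spot in each array. For a single channel this SD was larger, from 0.18 to 0.21 in Cy3 and from 0.20 to 0.24 in Cy5. All values are log2 of the ratio, centred on each array's median.

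The whole-cell extract channel showed which DNA each strain lacked. IRD2 lost the signal of 2 short segments of the mating-type contig, at 19551 to 19810 (median log2 difference from WT -8.81) and 39251 to 39510 (-8.99), with 5 probes each. Both lie near the edges of, and inside, the silent mating-type region as analysed here (18701 to 40760). The double mutant lost the same segments (-8.35 and -8.59), and clr3D did not. A second set of tiles, on chromosome II at 2131111 to 2131320 and 2138611 to 2138820, showed the same losses in both IRD2 arrays (-8.51 and -8.71 in IRD2, -8.06 and -8.26 in the double mutant). No probe of clr3 was analysed here, so the deletion of that gene was not checked. The other runs of lower extract signal were shallower: all 8 in clr3D had medians between -1.06 and -1.34 and 7 of them lay in the mating-type contig.

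In WT cells the central domain of the centromere of chromosome II (1621061 to 1630970), where the H3 variant CENP-A replaces much of H3, held the least new H3. Its median ratio was -3.10 (SD between probes 0.35, 198 probes), and it was -3.18 in clr3D, -3.31 in IRD2 and -3.31 in the double mutant, below all 10000 random stretches of the arms in each array. The outer repeats on both sides, which carry heterochromatin, stood close to the array median in WT (0.084, SD 0.38, 590 probes), as did the right end of chromosome II (-0.02, SD 0.41, 999 probes) and the silent mating-type region (-0.16, SD 0.41, 441 probes). Transfer RNA genes had low ratios everywhere: the 41 measured tRNA genes had a median of -0.83 in WT, -0.67 in clr3D, -1.40 in IRD2 and -0.97 in the double mutant. The 25 ribosomal protein genes stood at 0.26 in WT, and the 3 measured core histone genes had a median of 0.79, with hht2, which encodes H3, at 1.504 and pht1, the H2A.Z gene, at -0.48.

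**Figure D1:**
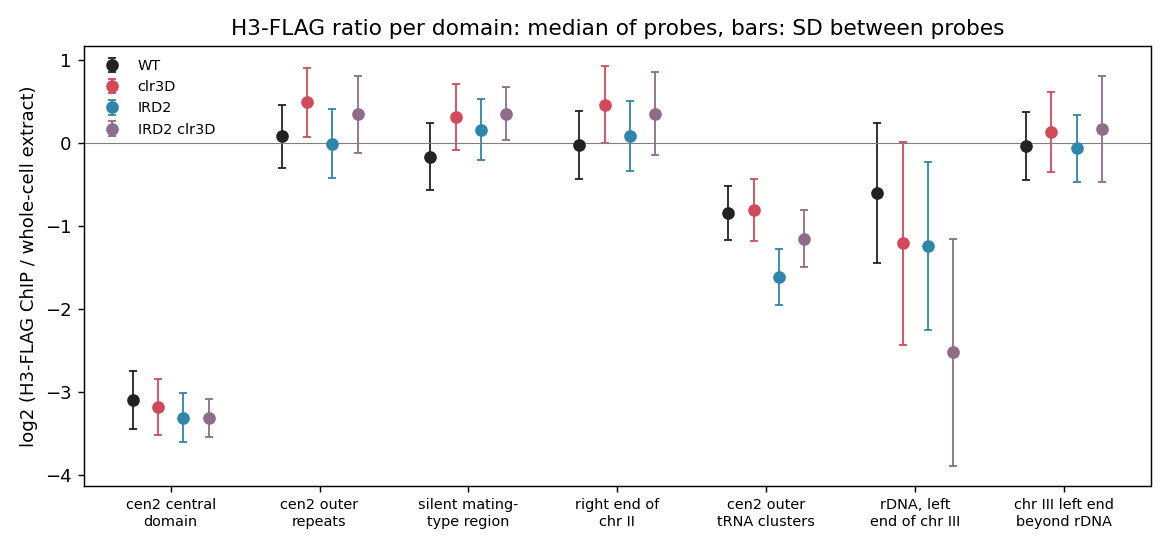
Median log2 ratio of H3-FLAG ChIP over whole-cell extract (y axis) for 7 domains (x axis) in the 4 arrays, coloured by genotype; points are medians over probes and bars the SD between probes of 1 array. The central domain of the centromere lies near -3.10 in WT and below -3 in the other arrays, while the outer repeats lie at 0.084 in WT and 0.49 in clr3D.

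Deleting clr3 was compared with WT to ask whether this deacetylase limits the entry of new H3 into heterochromatin. In clr3D the ratio was higher by 0.40 over the outer repeats (SD between probes 0.13), by 0.43 over the silent mating-type region (SD 0.23) and by 0.48 over the right end of chromosome II (SD 0.25), each above all 10000 random stretches. The share of probes with a positive difference was 99.0%, 97.7% and 92.8%. The central domain differed by -0.086, within the range of random stretches (percentile 26.6; 0.072 with normexp), and the tRNA gene clusters that border the centromere by 0.020 (-0.14 with Cy5 alone). The ribosomal RNA genes at the left end of chromosome III differed by -0.49, where the extract signal was higher by 0.47 and Cy5 alone turned to 0.071. The extract signal was lower in clr3D over the outer repeats, the mating-type region and the right end, by a median of -0.50, -0.79 and -0.35, and with the Cy5 channel alone the differences were -0.098, -0.30 and 0.12. With loess within each array the difference over the outer repeats was 0.14, and with probes matching 1 place only that over the mating-type region was 0.24. Such probes leave out the middle of that region, and without probes of many copies its difference was 0.44.

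Of single genes, 9 of the 10 with the highest clr3D minus WT difference lay at the right end of chromosome II. They include tlh2, a helicase gene of the chromosome end (0.52, SD between probes 0.13, 120 probes at 4528701 to 4534710), SPBPB2B2.16c (0.62), SPBPB2B2.15 (0.54), ftm7 (0.53), SPBPB2B2.19c (0.53), SPBPB2B2.18 (0.51), SPBCPT2R1.03 (0.50), gal1, a galactokinase gene (0.48), and SPBCPT2R1.01c (0.46). The other is hsp16, which encodes a small heat shock protein (0.70, SD 0.13, 18 probes at 2661911 to 2662820 of chromosome II), of which 9 probes were not well above background in every array. The lowest differences were at nmt1, a thiamine biosynthesis gene (-0.71, SD 0.10, 25 probes), and fmo1 (-0.62), followed by the histone genes hht2 (-0.45) and hhf2 (-0.43), which encode H3 and H4. Then came isp4 (-0.40), trz2 (-0.38), mis15, a kinetochore gene (-0.37), SPBC83.12 (-0.37), inv1, the invertase gene (-0.36), and hmt2 (-0.34). With Cy5 alone tlh2 differed by 0.12, SPBPB2B2.15 by 0.053 and SPBCPT2R1.01c by 0.096, and 8 of the 10 highest and 8 of the 10 lowest differences were smaller by over 1.5 times, with none of the other sign. Whether DNA of the H3-FLAG plasmid, named for inv1 and H3.2, also bound the tiles of inv1 and hht2 was not tested.

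Among the lists, the 3 measured core histone genes had a median clr3D minus WT difference of -0.43 (-0.16 with Cy5 alone), with 2 of 3 below 0 and pht1 at 0.24. The 25 ribosomal protein genes had a median of -0.083, with 20 of them below 0 (percentile 0.62 among random lists), and it was 0.013 with Cy5 alone. Of the list of glycolysis and translation genes, 3 glycolytic genes (eno101, fba1 and tdh1) and the actin gene act1 were measured, and no translation gene. The medians were 0.045 for these 4 genes (0.25 with Cy5 alone), 0.048 for the tRNA genes (-0.12 with Cy5 alone), -0.036 for the 3 core stress genes, 0.036 for the 3 meiotic genes and 0.026 for the 3 auxotrophy marker genes, all between the 2.5 percentile of random lists and its upper counterpart. For the tRNA genes the random lists held protein-coding genes and are not a matched set.

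IRD2 was compared with WT to ask what the loss of the segments near the edges of the silent mating-type region goes with. Probes of the lost segments are part of the median of that region. The mating-type region had a higher ratio in IRD2, by 0.32 (SD between probes 0.37, 76.9% of probes above 0), above all random stretches. Over the outer repeats the difference was -0.093 (percentile 18.2) and over the right end of chromosome II 0.11 (percentile 96.3; -0.0048 with probes matching 1 place only). The central domain differed by -0.20 (percentile 7.47), and by -0.39 with Cy5 alone. It turned to 0.29 with normexp and was -0.77 after scaling to one median absolute deviation. The tRNA clusters at the centromere borders differed by -0.76 (SD 0.21, no probe above 0), and the ribosomal RNA genes by -0.54 (SD 0.24), where the extract signal was higher by 0.47 and Cy5 alone differed by -0.077. At the tRNA clusters the extract signal was higher in IRD2 by 0.72, and Cy5 alone differed by -0.081. Over the mating-type region Cy5 alone differed by -0.058 and the extract signal by -0.30. The ratio difference there was 0.20 with probes matching 1 place only, which leave out the region's middle. It was 0.39 (89.8% of probes above 0) without probes of many copies.

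**Figure D2:**
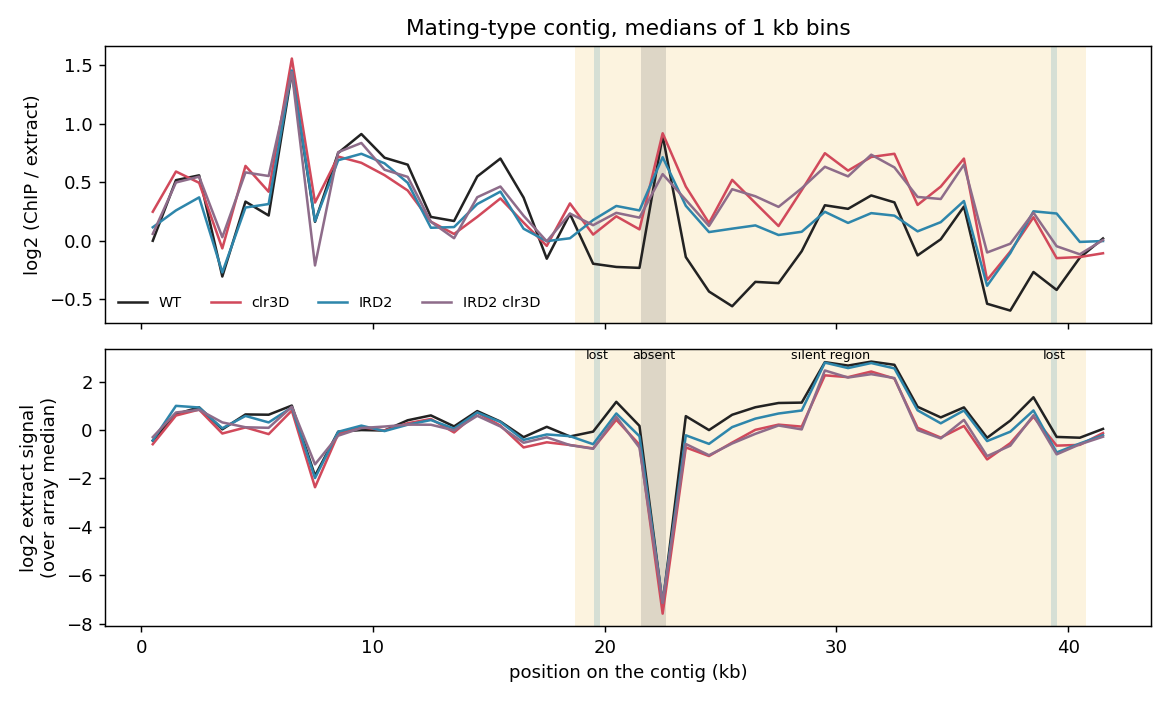
Medians of 1 kb bins along the mating-type contig (x axis, kb) for the log2 ratio (upper panel) and the log2 whole-cell extract signal over the array median (lower panel), 1 line per genotype. Shading marks the silent region, the segments lost in IRD2 at 19551 to 19810 and 39251 to 39510, and a stretch without extract signal in all 4 arrays; in the silent region the WT line runs below the 3 mutant lines in most bins of the upper panel.

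The genes with the lowest IRD2 minus WT difference were hsp16 (-2.65, SD between probes 0.38; -2.48 over its probes well above background), the enolase gene eno101 (-1.80, SD 0.29, 29 probes at 2203011 to 2204470 of chromosome II), the aldolase gene fba1 (-1.40, SD 0.20, 26 probes at 1690111 to 1691420), nmt1 (-1.04) and the glyceraldehyde-3-phosphate dehydrogenase gene tdh1 (-0.74). The coactivator gene mbf1 (-0.69), mug124 (-0.67), SPBC32H8.15 (-0.60), hht2 (-0.58) and aha1 (-0.57) followed. For eno101 and fba1 the Cy5 channel alone differed by -1.90 and -1.35. SPBC32H8.15 differed by 0.041 in Cy5 alone and by 0.65 in the extract, and hht2 by -0.15 in Cy5 alone. Upward differences were smaller: SPBC18E5.14c (0.36), nhm1 (0.36), ftm7 (0.35), sld5, a replication gene (0.32), sen34 (0.32), pop4 (0.31), mcs2 (0.31), SPBC18E5.08 (0.28), SPBPB2B2.19c (0.28) and pof2 (0.28), of which 5 of 10 were smaller by over 1.5 times with Cy5 alone.

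The 3 glycolytic genes and act1 had a median IRD2 minus WT difference of -1.07, and all 4 were below 0, with act1 at -0.15 (0.045 with Cy5 alone); the median was -0.57 with normexp. All 41 tRNA genes were below 0, with a median of -0.63, while their extract signal had a median of 0.43 and Cy5 alone -0.056. Of the 25 ribosomal protein genes, 24 were below 0 (median -0.24, and -0.14 with Cy5 alone). The medians were -0.54 for the core histone genes (2 of 3 below 0, with pht1 at 0.016; -0.15 with Cy5 alone) and -0.40 for the core stress genes (3 of 3 below 0; -0.042 with Cy5 alone and 0.41 in the extract), where gpx1, a glutathione peroxidase gene, was at -0.40 (0.0069 with Cy5 alone) and atf1, a stress transcription factor gene, at -0.24 (-0.042 with Cy5 alone). These 5 medians lay under the 2.5 percentile of random lists, which for the tRNA genes held protein-coding genes and are not a matched set. The auxotrophy marker genes (-0.17, and -0.0057 with Cy5 alone) and the meiotic genes (0.059) did not.

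In the double mutant, compared with WT, the ratio was higher over the mating-type region by 0.44 (SD between probes 0.31), over the right end of chromosome II by 0.42 (SD 0.32) and over the outer repeats by 0.26 (SD 0.14, percentile 97.9). The ribosomal RNA genes at the left end of chromosome III differed by -1.80 (SD 0.62, 461 probes at 1 to 23120), the largest domain difference from WT in the series, with 1.09 in the extract and -0.55 in Cy5. Beyond these genes, the left end of chromosome III differed by 0.12 (percentile 85.2). The tRNA clusters differed by -0.27 (percentile 6.05; -0.45 with Cy5 alone) and the central domain by -0.21 (percentile 11.5), which turned to 0.27 with normexp and was -0.014 with loess. With Cy5 alone the outer repeats, the mating-type region and the right end of chromosome II differed by -0.22, -0.30 and 0.18. The outer repeats differed by 0.094 with loess, and the right end of chromosome II by 0.23 with probes matching 1 place only.

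Upward gene differences of the double mutant from WT were led by tlh2 (0.57), SPBCPT2R1.03 (0.53), SPBPB2B2.19c (0.52), ftm7 (0.50) and SPBPB2B2.15 (0.48) of the right end of chromosome II. Next were lvs1 (0.43), the Mediator gene med15 (0.42), sld5 (0.41) and the mating-type genes mat1-Mi (0.37) and mat3-Mi (0.37), whose Cy5 alone differed by -0.19 and -0.23. The ratios of mat1-Mi and mat3-Mi were near equal, at 0.58 and 0.59 in the double mutant and 0.20 and 0.22 in WT. Whether their tiles read separate DNA was not tested. With Cy5 alone tlh2 differed by 0.045 (-0.51 in the extract), and 9 of these 10 were smaller by over 1.5 times or of the other sign. The lowest were fba1 (-1.20), eno101 (-1.10), hsp16 (-1.03), nmt1 (-0.997), SPBC1921.04c (-0.82), hhf2 (-0.68), SPBC21B10.15 (-0.65), inv1 (-0.62), hht2 (-0.61) and fmo1 (-0.57), of which 6 of 10 were smaller by over 1.5 times with Cy5 alone. The list medians were -0.83 for the glycolytic genes and act1 (4 of 4 below 0), -0.61 for core histones (2 of 3 below 0, with pht1 at 0.044; -0.11 with Cy5 alone), -0.42 for core stress (3 of 3 below 0; -0.22 with Cy5 alone), -0.24 for tRNA genes (38 of 41 below 0) and -0.11 for ribosomal protein genes (22 of 25 below 0). They were 0.073 for meiotic genes and 0.029 for auxotrophy marker genes. With normexp the medians of the glycolytic genes with act1 and of tRNA genes were -0.38 and -0.12.

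Deleting clr3 in cells that were already IRD2 was examined by setting the double mutant against IRD2. The ratio was higher by 0.37 over the outer repeats (SD between probes 0.16), by 0.29 over the right end of chromosome II (SD 0.23) and by 0.20 over the mating-type region (SD 0.35), each above all random stretches. It was also higher over the tRNA clusters, by 0.47, and over the left end of chromosome III beyond the ribosomal RNA genes, by 0.18, while those genes differed by -1.20 (-0.51 with Cy5 alone). Without probes of many copies the mating-type difference was 0.13, and over the 197 tiles of the same region on chromosome II, which leave out its middle, it was -0.015 (SD 0.39, percentile 42.3). Loess gave 0.15 over the outer repeats, and Cy5 alone gave -0.056 there, -0.27 over the mating-type region, -0.42 over the tRNA clusters and 0.056 over the right end of chromosome II. The gene with the highest difference was hsp16 (1.63, SD 0.35), then SPBC32H8.15 (0.93), eno101 (0.70), tlh2 (0.56), SPCP20C8.02c (0.51), aha1 (0.36), the DNAJ chaperone gene mas5 (0.36), mat3-Mi (0.34), rrb1 (0.33) and rpp202 (0.32). The lowest were tfb5 (-0.48), prp38 (-0.36), SPBC1921.04c (-0.31), cox7 (-0.29), mcp4 (-0.28), ask1 (-0.27), sfr1 (-0.26), cho1 (-0.25), SPBC336.16 (-0.25) and mrps28 (-0.23). With Cy5 alone tlh2 differed by 0.052 and eno101 by 0.21 (-0.51 and -0.49 in the extract), and 4 of the 10 highest and 9 of the 10 lowest were smaller by over 1.5 times or of the other sign. List medians were 0.34 for tRNA genes (38 of 41 above 0), 0.19 for the glycolytic genes and act1 (4 of 4 above 0) and 0.098 for ribosomal protein genes (23 of 25 above 0). With Cy5 alone these were -0.21, -0.079 and 0.046. The other medians were 0.097 for auxotrophy markers, -0.022 for core histones, 0.014 for core stress and 0.00095 for meiotic genes.

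**Figure D3:**
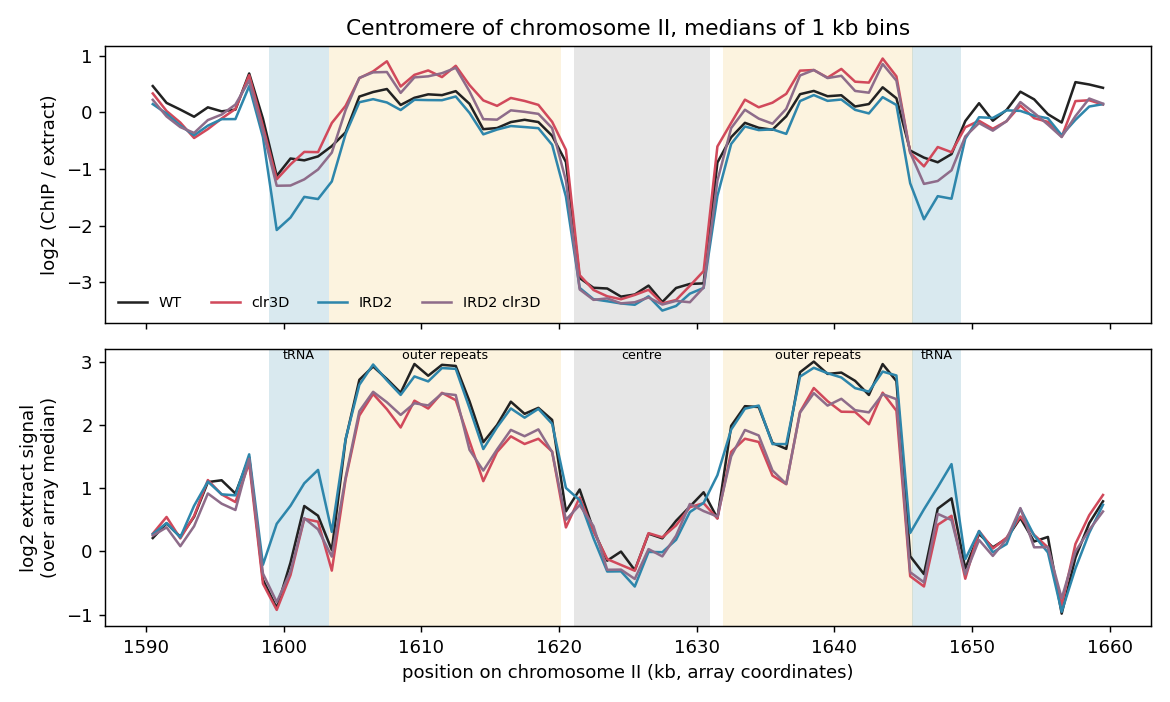
Medians of 1 kb bins along the centromere of chromosome II (x axis, kb in array coordinates) for the log2 ratio (upper panel) and the log2 whole-cell extract signal over the array median (lower panel), 1 line per genotype. In most bins of the outer repeats, though not in all at their edges, the clr3D and IRD2 clr3D lines run above WT and IRD2 in the ratio, and they run below them in the extract; over the tRNA clusters IRD2 is lowest in the ratio (median -1.61).

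The double mutant was also set against clr3D, which asks what IRD2 adds once Clr3 is gone. The mating-type region differed by 0.0044 (percentile 50.3) and the right end of chromosome II by -0.035 (percentile 12.8), which turned to 0.029 with Cy5 alone. The outer repeats differed by -0.12 (percentile 1.82; -0.026 with probes matching 1 place only), the tRNA clusters by -0.31 (percentile 0.57) and the ribosomal RNA genes by -1.28 (-0.63 with Cy5 alone). The central domain differed by -0.18 (percentile 3.31), but by 0.21 with normexp and 0.0013 with loess. The left end of chromosome III beyond the ribosomal RNA genes differed by 0.034 (0.18 with Cy5 alone). The lowest genes were hsp16 (-1.73), fba1 (-1.20), eno101 (-1.15), tdh1 (-0.90, SD between probes 0.64), SPBC1921.04c (-0.68), SPBC21B10.15 (-0.62), prp38 (-0.52), tfb5 (-0.50), gem7 (-0.44) and cut2, the securin gene (-0.42). The highest were SPBC32H8.15 (0.47), the chaperonin gene cct3 (0.26), new15 (0.23), sld5 (0.23), the replicative helicase gene mcm2 (0.21), pop8 (0.18), apc13 (0.15), SPBC146.02 (0.14), SPCP20C8.02c (0.13) and kgd4 (0.12). With Cy5 alone 4 of the 10 lowest and 3 of the 10 highest were smaller by over 1.5 times. List medians were -1.03 for the glycolytic genes and act1 (4 of 4 below 0; -0.60 with normexp) and -0.29 for tRNA genes (39 of 41 below 0; -0.15 with normexp). They were -0.28 for core stress, -0.20 for core histones, -0.025 for ribosomal protein genes, 0.023 for meiotic genes and 0.017 for auxotrophy markers. With Cy5 alone core stress was at -0.049, core histones turned to 0.051, ribosomal protein genes were at -0.086 and auxotrophy markers turned to -0.093.

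Both backgrounds were put in 1 additive limma fit to test the genes, 897 in all, with 1 residual degree of freedom each. That residual is the disagreement between backgrounds, which the fit takes as error. No replicate culture or array enters its p-values. For the clr3 term 25 genes passed, 21 higher and 4 lower with clr3 deleted. Higher were hsp16 (1.16, SE 0.084), tlh2 (0.54; adjusted p = 6.38e-08 by limma), SPBPB2B2.16c (0.41), gal1 (0.40), SPBCPT2R1.03 (0.39), SPBC32H8.15 (0.39), SPBPB2B2.19c (0.38), eno101 (0.38), SPBPB2B2.15 (0.38) and mat1-Mi (0.37). The 4 lower genes were fmo1 (-0.36; adjusted p = 0.00142 by limma), nmt1 (-0.34), sua1 (-0.28) and hhf2 (-0.28). The term is an average over backgrounds, and for 18 of the 25 genes these differed by over 1.5 times or in sign: deleting clr3 went with -0.14 at SPBC32H8.15 and 0.058 at eno101 in WT cells but 0.93 and 0.70 in IRD2 cells. Conversely nmt1, fmo1 and sua1 were at -0.71, -0.62 and -0.52 in WT cells but at 0.039, -0.097 and -0.052 in IRD2 cells. Besides mat1-Mi, the higher genes included mat3-Mi (0.35), mat1-Mc (0.34) and mat3-Mc (0.33). Whether the tiles of mat1 and mat3 read separate DNA was not tested, so these may not be separate signals. For the IR term 46 genes passed, 1 higher and 45 lower in the IRD2 arrays. The higher gene was sld5 (0.27; adjusted p = 0.0261 by limma), a call that ended with loess (0 higher, 44 lower), after scaling to one median absolute deviation (0 and 21), and without the clr3 state (0 and 13). The lowest were hsp16 (-2.19), eno101 (-1.48; adjusted p = 2.17e-57 by limma), fba1 (-1.30), tdh1 (-0.82), nmt1 (-0.66), SPBC1921.04c (-0.60), mbf1 (-0.55), SPBC21B10.15 (-0.50), cut2 (-0.45) and gem7 (-0.44). All 46 had the same sign in both backgrounds, but 29 differed by over 1.5 times between them, such as nmt1 (-1.04 in WT cells and -0.28 in clr3D cells) and mbf1 (-0.69 and -0.40). In this fit limma estimated an infinite prior, so every gene has the SE of 0.084 and the very small p-values rest on 1 spread shared by all genes. With each gene's own spread 0 genes passed for either term, while 61 and 51 had an unadjusted p under 0.05 by limma's fit without moderation. The 4 lower clr3 genes, SPBC32H8.15 and eno101 lost their call with normexp and with the scaling, as did hsp16 (in both terms), SPBPB2B2.19c and, in the IR term, SPBC21B10.15 with normexp alone. The clr3 count was 11 with normexp (11 higher, 0 lower), 10 after scaling the arrays to one median absolute deviation (10 and 0), 29 with loess (16 and 13) and 0 without the IR state in the limma model, where 61 had an unadjusted p under 0.05; the IR count was 21 with the scaling and 13 without the clr3 state.

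Across the 897 genes the clr3D minus WT difference had a Pearson r of 0.342 and a Spearman rho of 0.289 with the double mutant minus IRD2 difference, which shares no array with it. The sign was the same for 59.9% of genes. Without the genes of the right end of chromosome II and the mating-type loci, chosen after the values were seen, r was 0.274 over 881 genes. Over the 7 domains, which include the heterochromatic ones, the signs were the same for all 7, for 6 with loess, normexp or the scaling, where the central domain differed, and for 4 with Cy5 alone. There the central domain (-0.11 and 0.017), the ribosomal RNA genes (0.071 and -0.51) and the left end of chromosome III beyond them (-0.052 and 0.23) had opposite signs. Genes and domains are not independent replicates, and no p-value was computed.

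**Figure D4:**
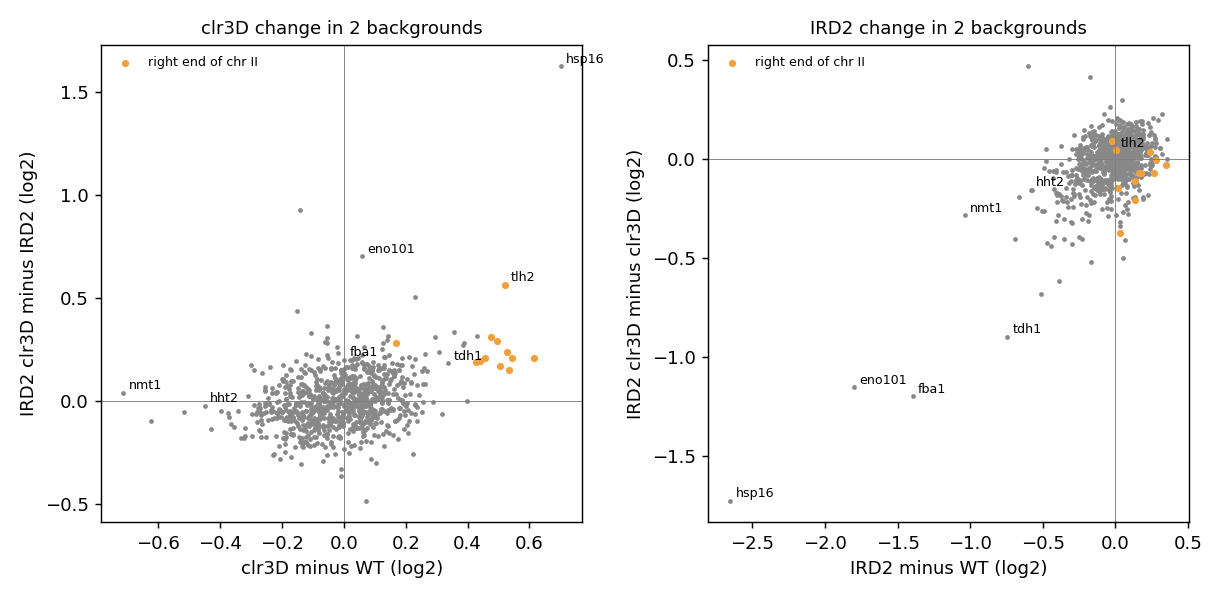
Differences in mean log2 ratio for 897 protein-coding genes, 1 point per gene: the clr3D change in WT (x axis, log2) against that in IRD2 (y axis, log2) on the left, and the IRD2 change in WT (x axis) against that in clr3D (y axis) on the right. Genes of the right end of chromosome II are coloured; tlh2 lies at 0.52 and 0.56 on the left, and hsp16 at -2.65 and -1.73 on the right.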

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

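Chosen only after the results were seen were the tests on the whole-cell extract signal of the 3 patterns below, the normexp test on the glycolytic genes and the loess test on the mating-type region and chromosome end by themselves; the other tests were written down before.

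The ratio was higher over heterochromatin in clr3D than in WT. Dependence on spot brightness did not account for the mating-type region and the right end of chromosome II, where loess left at least 83.8% of the difference, but it cannot be told apart over the outer repeats, where loess left 35.7%. The tables argue against GC content of the probes, since at least 96.6% was left over the outer repeats and the chromosome end once a line on GC was removed; for the mating-type region only 34.7% of probes had a GC value. A lower whole-cell extract signal fits: it made up 72.0% of the difference at the chromosome end, 124.8% over the outer repeats and 183.2% over the mating-type region. Loss of Clr3 itself may change both channels, and with 1 array per genotype this stays open and untested.

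The glycolytic genes eno101, fba1 and tdh1 had lower ratios in IRD2 than in WT; the values below are for the list median over these and act1, which was at -0.15. Dependence on brightness does not account for this, since loess left 94.4% of the difference, nor does a higher extract signal, which made up 11.03%. Only 1 of the 121 probes was not well above background, so by that measure few spots of these genes lay close to it. Leaving that probe out kept 99.3% of the difference. It could hardly move the median, so this test cannot tell. Background correction cannot be told apart, as normexp left 53.5% (median -0.57), too near the 50% set as the bound. The double mutant minus clr3D difference, which shares no array with this one, had a median of -1.03 with 4 of 4 genes below 0 (-0.60 with normexp, -1.52 with Cy5 alone). Whether the cultures of the IRD2 genotypes were handled together is not known here, so the second pair does not exclude a difference between cultures. Genotype, and growth or induction that goes with it, stay open and untested.

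The ribosomal RNA genes of chromosome III had a lower ratio in the double mutant than in WT. Brightness does not account for it, as loess left 110.7% of the difference. A higher extract signal (1.09) made up 60.6% of it, and Cy5 alone differed by -0.55. More copies of this DNA by themselves would raise both channels, which here differed in opposite directions. The 60.6% follows from how the ratio is built and does not decide between causes. Genotype stays open, untested.

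The ribosomal protein genes drew attention because the median difference after deleting clr3 was -0.083 in WT cells and 0.098 in IRD2 cells. With Cy5 alone these were 0.013 and 0.046, so the opposite signs are absent there; this contrast was not tested. The whole-cell extract channel, which serves only as the divisor, differed by itself between arrays. Its median over the outer repeats differed from WT by -0.50 in clr3D and -0.47 in the double mutant, over the mating-type region by -0.79 and -0.75, and over the right end of chromosome II by -0.35 in clr3D and -0.23 in the double mutant. It was higher over the tRNA clusters in IRD2, by 0.72, and over the ribosomal RNA genes, by 0.47 in clr3D, 0.47 in IRD2 and 1.09 in the double mutant.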

How the results depend on the processing

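No paired analysis was possible because each genotype has 1 array. Chosen only after the results were seen were the tests with Cy5 alone, without probes of many copies, without heterochromatin genes, with robust eBayes, without moderation, of the signs over domains, of the contrast between backgrounds, and all those of single genes; the other settings were planned before the data were examined. Of the differences of domains, 263 stayed within the spread of random stretches, 73 moved further, and 9 had lain outside the central range of random stretches and turned their sign. For levels of domains these counts were 186, 51 and 7, for list differences 196, 46 and 3, and for list levels 152, 16 and 0. The values of single named genes and list members stayed alike in 1150 cases, moved in 209, lost their call in 58 and turned in 8. For the contrast of the clr3 difference between backgrounds 39 stayed, 14 moved and 2 turned. Counting values inside the central range too, the sign turned for 28 differences of domains, 15 levels of domains, 14 list differences, 4 list levels, 7 contrasts and 64 values of single genes. Nothing moved beyond that spread with the authors' series matrix, centring on the chromosome arms, probes well above background only, 1 or 5 probes per gene, robust eBayes, or background-subtracted signals for the runs of lost extract DNA. Some of these settings could move little by construction. The series matrix holds the same ratio as the main value, the background filter leaves out few probes, and robust eBayes kept the infinite prior. The values that stayed alike include 358 from the series matrix and 357 from that filter. Their number therefore overstates how far the processing was varied. Except where the setting explains the shift by its construction, the cause was not tested. Signal over background limits few probes, since at least 43811 of 43993 were well above it in both channels, but it limits hsp16, with 9 of 18 probes below that level. A 100 kb chromosome end was not run, as the tiles used here span 50 kb, and neither were the planned domains that are not among these tiles.

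Normexp moved levels and differences of domains and lists as follows. The central domain of the centromere had levels of -2.49 in WT, -2.41 in clr3D, -2.06 in IRD2 and -2.13 in the double mutant, and differences of 0.072 for clr3D minus WT, 0.29 for IRD2 minus WT, 0.27 for double minus WT and 0.21 for double minus clr3D. The outer repeats had levels of -0.071 in WT, -0.16 in IRD2 and 0.20 in the double mutant. The right end of chromosome II had a level of -0.12 in WT, and differences of 0.59 for clr3D minus WT and 0.35 for double minus IRD2. The tRNA clusters had a level of -2.07 in IRD2, and differences of -1.03 for IRD2 minus WT and 0.76 for double minus IRD2. The ribosomal RNA genes had levels of -0.78 in WT, -1.47 in clr3D, -1.47 in IRD2 and -3.01 in the double mutant, and differences of -2.14 for double minus WT, -1.47 for double minus IRD2 and -1.59 for double minus clr3D. The core histone genes had levels of 1.10 in WT, 0.55 in clr3D and 0.40 in IRD2, and a difference of -0.54 for clr3D minus WT. The glycolysis and translation genes had levels of -0.44 in IRD2 and -0.25 in the double mutant, and differences of -0.57 for IRD2 minus WT, -0.38 for double minus WT and -0.60 for double minus clr3D. The ribosomal protein genes had a level of 0.39 in WT, and differences of -0.34 for IRD2 minus WT, -0.16 for double minus WT and -0.063 for double minus clr3D. The tRNA genes had levels of -1.65 in IRD2 and -0.83 in the double mutant, and differences of -0.12 for double minus WT, 0.43 for double minus IRD2 and -0.15 for double minus clr3D. The mating-type region had differences of 0.57 for clr3D minus WT and 0.60 for double minus WT.

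Loess within each array moved these values. The central domain of the centromere had levels of -3.13 in IRD2 and -2.996 in the double mutant, and differences of -0.014 for double minus WT, 0.10 for double minus IRD2 and 0.0013 for double minus clr3D. The outer repeats had levels of -0.24 in WT, -0.10 in clr3D, -0.28 in IRD2 and -0.15 in the double mutant, and differences of 0.14 for clr3D minus WT, 0.094 for double minus WT and 0.15 for double minus IRD2. The mating-type region had a level of 0.16 in clr3D. The right end of chromosome II had levels of -0.18 in WT, 0.20 in clr3D, -0.054 in IRD2 and 0.13 in the double mutant, and a difference of 0.20 for double minus IRD2. The ribosomal RNA genes had levels of -0.83 in WT, -1.72 in clr3D, -1.50 in IRD2 and -2.96 in the double mutant, and differences of -0.65 for clr3D minus WT, -1.99 for double minus WT and -1.39 for double minus IRD2. The glycolysis and translation genes had a level of -0.41 in the double mutant, and differences of -0.62 for double minus WT, 0.32 for double minus IRD2 and -0.79 for double minus clr3D. The ribosomal protein genes had levels of 0.20 in WT, 0.093 in clr3D and 0.070 in the double mutant, and a difference of 0.066 for double minus IRD2. The tRNA genes had levels of -0.77 in WT and -0.87 in the double mutant, and differences of -0.11 for double minus WT, 0.41 for double minus IRD2 and -0.18 for double minus clr3D. The tRNA clusters had a difference of 0.56 for double minus IRD2. The core histone genes had differences of -0.16 for double minus IRD2 and -0.089 for double minus clr3D.

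Scaling the arrays to one median absolute deviation moved fewer. The central domain of the centromere had a level of -3.71 in IRD2, and differences of -0.77 for IRD2 minus WT, -0.44 for double minus WT, 0.31 for double minus IRD2 and -0.42 for double minus clr3D. The tRNA clusters had a level of -1.81 in IRD2, and differences of -0.995 for IRD2 minus WT and 0.64 for double minus IRD2. With the scaling, the ribosomal RNA genes had a level of -1.39 in IRD2, and differences of -0.76 for IRD2 minus WT, -1.09 for double minus IRD2 and -1.42 for double minus clr3D. The tRNA genes had levels of -0.78 in WT and -1.57 in IRD2, and differences of -0.82 for IRD2 minus WT, -0.30 for double minus WT, 0.49 for double minus IRD2 and -0.36 for double minus clr3D. The core histone genes had differences of -0.38 for IRD2 minus WT and -0.12 for double minus IRD2. The glycolysis and translation genes had a difference of 0.29 for double minus IRD2.

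Extending each domain by 5 kb takes in neighbouring DNA by construction. The central domain of the centromere had levels of -2.54 in WT, -2.56 in clr3D, -2.85 in IRD2 and -2.91 in the double mutant, and differences of 0.21 for clr3D minus WT, -0.0092 for double minus WT and 0.13 for double minus IRD2. The outer repeats had levels of -0.27 in WT, 0.062 in clr3D, -0.40 in IRD2 and -0.16 in the double mutant. The tRNA clusters had levels of -0.021 in WT, -0.15 in clr3D, -0.17 in IRD2 and -0.13 in the double mutant, and differences of -0.24 for IRD2 minus WT, -0.10 for double minus WT, 0.33 for double minus IRD2 and -0.092 for double minus clr3D. After extension, the mating-type region had a difference of 0.18 for IRD2 minus WT. After extension, the ribosomal RNA genes had differences of -0.39 for clr3D minus WT and -1.12 for double minus IRD2.

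Keeping only probes that match 1 place in the reference leaves out most repeats by construction. It also leaves out the middle of the mating-type region, repeated or not, as that has no counterpart in the reference. The values of that region below are therefore for its outer parts. The outer repeats had levels of -0.46 in WT, -0.022 in clr3D, -0.50 in IRD2 and -0.20 in the double mutant, and differences of 0.31 for clr3D minus WT and -0.026 for double minus clr3D. The mating-type region had levels of -0.35 in WT, -0.084 in clr3D, -0.089 in IRD2 and 0.029 in the double mutant, and differences of 0.24 for clr3D minus WT, 0.20 for IRD2 minus WT and 0.088 for double minus clr3D. The right end of chromosome II had levels of 0.17 in clr3D, -0.19 in IRD2 and -0.049 in the double mutant, and differences of 0.35 for clr3D minus WT, -0.0048 for IRD2 minus WT, 0.23 for double minus WT and -0.13 for double minus clr3D.

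Taking the mean over probes in place of the median moved 8 values. As a mean, the ribosomal RNA genes had levels of -0.35 in WT, -0.66 in clr3D, -0.84 in IRD2 and -1.91 in the double mutant, and differences of -0.31 for clr3D minus WT, -1.56 for double minus WT and -1.07 for double minus IRD2. As a mean, the mating-type region had a difference of 0.13 for double minus IRD2.

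The Cy5 signal alone, chosen after the data were seen, drops the division by whole-cell extract. Between near-identical tiles of an array its SD per spot was 0.20 to 0.24, against 0.07 for the ratio. That SD is for single spots and does not measure the spread of a median over many probes. With 1 array per genotype the sign of values near 0 stays uncertain. Among random stretches, clr3D minus WT in Cy5 lay at percentile 3.78 over the outer repeats. It lay at percentile 0 over the mating-type region and 99.85 over the right end of chromosome II. The central domain of the centromere had differences of -0.39 for IRD2 minus WT, -0.38 for double minus WT and -0.30 for double minus clr3D. The outer repeats had differences of -0.10 for clr3D minus WT, -0.22 for double minus WT and -0.056 for double minus IRD2. In Cy5, the mating-type region had differences of -0.30 for clr3D minus WT, -0.058 for IRD2 minus WT, -0.30 for double minus WT and -0.27 for double minus IRD2. The right end of chromosome II had differences of 0.12 for clr3D minus WT, 0.18 for double minus WT, 0.056 for double minus IRD2 and 0.029 for double minus clr3D. The tRNA clusters had differences of -0.14 for clr3D minus WT, -0.081 for IRD2 minus WT, -0.45 for double minus WT and -0.42 for double minus IRD2. In Cy5, the ribosomal RNA genes had differences of 0.071 for clr3D minus WT, -0.077 for IRD2 minus WT, -0.55 for double minus WT, -0.51 for double minus IRD2 and -0.63 for double minus clr3D. The left end of chromosome III beyond them had differences of -0.052 for clr3D minus WT and 0.18 for double minus clr3D. The core histone genes had differences of -0.16 for clr3D minus WT, -0.15 for IRD2 minus WT, -0.11 for double minus WT and 0.051 for double minus clr3D. The core stress genes had differences of -0.042 for IRD2 minus WT, -0.22 for double minus WT and -0.049 for double minus clr3D. The glycolysis and translation genes had differences of 0.25 for clr3D minus WT, -0.96 for IRD2 minus WT, -1.12 for double minus WT, -0.079 for double minus IRD2 and -1.52 for double minus clr3D. The auxotrophy markers had differences of -0.0057 for IRD2 minus WT and -0.093 for double minus clr3D. The ribosomal protein genes had differences of 0.013 for clr3D minus WT, -0.14 for IRD2 minus WT, 0.046 for double minus IRD2 and -0.086 for double minus clr3D. The tRNA genes had differences of -0.12 for clr3D minus WT, -0.056 for IRD2 minus WT, -0.31 for double minus WT, -0.21 for double minus IRD2 and -0.18 for double minus clr3D. Among genes named for a difference by its size, those of the other sign were SPBC32H8.15 (0.041 for IRD2 minus WT), mat1-Mi (-0.19 for double minus WT), mat3-Mi (-0.23 for double minus WT), SPBC336.16 (0.022 for double minus IRD2), cho1 (0.068 for double minus IRD2), mat3-Mi (-0.10 for double minus IRD2), mrps28 (0.024 for double minus IRD2) and rpp202 (-0.039 for double minus IRD2). Members named as examples of a list turned too, such as gpx1 (0.0069) and act1 (0.045) for IRD2 minus WT, fba1 (-0.43) for double minus IRD2 and hht2 (0.051) for double minus clr3D.

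In the limma fit, the clr3 term had 25 genes (21 higher, 4 lower) against 11 with normexp (11 and 0), 10 with the scaling (10 and 0) and 29 with loess (16 and 13), so that each of these moved the split between directions. Without the other factor in the limma model it had 0, with 61 at an unadjusted p under 0.05, and without moderation 0, with 61. The IR term had 46 genes against 21 with the scaling, 13 without the other factor, and 0 without moderation in limma, with 51 at an unadjusted p under 0.05. The correlation of the gene differences between backgrounds was 0.274 without heterochromatin genes against 0.342. The 2 clr3 differences had the same sign in 4 of 7 domains with Cy5 alone. Without probes of many copies the double minus IRD2 difference of the mating-type region was 0.13. With Cy5 alone the contrast of the clr3 difference between backgrounds turned to 0.070 over the mating-type region and to -0.27 over the tRNA clusters.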

Other observations

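Chosen only after the result was seen were the test of copy number and, for the contrast between backgrounds, the tests with other settings. Genes of lists with fewer than 3 measured members have values only. The genes cdc18 and yox1, targets of the S-phase factor MBF, had ratios of 0.57 and 0.23 in WT, 0.38 and -0.055 in clr3D, 0.31 and -0.071 in IRD2, and 0.38 and -0.13 in the double mutant. The retrotransposons Tf2-9 and Tf2-10 stood at 0.55 and 0.56 in WT and between 0.62 and 0.66 in the other arrays. Of heterochromatin factor genes, clr1 was at -0.26 in WT and -0.0082 in the double mutant, and tas3 at -0.093 and -0.015. The invertase gene inv1 was at 1.04 in WT, 0.68 in clr3D, 0.55 in IRD2 and 0.42 in the double mutant. The phosphate genes had 0 measured members.

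In all 4 arrays the extract lacked DNA of 22 probes at 21551 to 22660 of the mating-type contig, with a median of -7.89 in WT and -8.82 in clr3D, and of 3 probes at 5701 to 5860. Chromosome II held such runs too, the longest of 22 probes at 2133111 to 2134220 (-7.92 in WT). Shorter ones lay elsewhere on it, such as 6 probes at 2902411 to 2902720 (-7.21 in WT). The contrast of the clr3 difference between backgrounds (in IRD2 minus in WT) was -0.27 over the mating-type region, -0.16 over the right end of chromosome II and -0.74 over the ribosomal RNA genes, each below all random stretches, and 0.47 over the tRNA clusters, above all of them. It was -0.023 over the outer repeats (percentile 32.9; 0.089 with probes matching 1 place only) and 0.053 over the central domain (percentile 66.5, and 0.12 with Cy5 alone). Over the left end of chromosome III beyond the ribosomal RNA genes the contrast was 0.084 (percentile 83.9), but 0.29 with Cy5 alone, above all random stretches. With Cy5 alone the contrast turned to 0.070 over the mating-type region and to -0.27 over the tRNA clusters, and it was -0.059 over the right end, 0.037 over the outer repeats and -0.56 over the ribosomal RNA genes. With probes matching 1 place only it was -0.11 over the mating-type region, whose middle they leave out, and -0.039 over the right end. With normexp it was 0.76 over the tRNA clusters. No difference between arrays has a replicate, so these percentiles describe these arrays only.

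A lower extract signal over heterochromatin of clr3D could reflect fewer copies of this DNA in hydroxyurea. The largest median difference of the 3 domains, -0.79, stays within the 1 log2 unit that replicated against unreplicated DNA allows, so this test neither excludes nor bears out the idea for the domains as a whole. Within the mating-type region some stretches go past that unit, with medians of -1.31 over 18 probes at 23051 to 23960 and -1.23 over 20 probes at 25251 to 26260 of the contig, which a change in copies within this range does not reach. These stretches were picked for their low signal, and the idea stays open. If copies were fewer, Cy5 would be lower too and the ratio would still be per copy.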
